A study of Saccharomyces cerevisiae with 26 samples.

How the data were processed

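Each of the 26 samples was a 2-colour array on total RNA of Saccharomyces cerevisiae grown in a galactose chemostat. Per the labels, the Cy3 channel of every array held the culture at t=0 and the Cy5 channel held it at 1 time after a transient glucose pulse of 2 g/l (14 times, 3 to 240 min) or 0.2 g/l (12 times, 2 to 150 min). Each time was measured on 1 array, so there were no replicate cultures and no arrays with the dyes exchanged. The deposited values are log2 ratios of both channels per spot, normalized by the authors, and the column medians over all spots lay between -0.118 and 0.028. The scale was inferred from the values. The direction was taken as Cy5 over Cy3, which the table itself does not state, and the normalization and the image software are not given in the sources used here. The design text of the series names only a regression correlation. Whether all arrays of a pulse used 1 extract of the t=0 culture is not given either.

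The table held 10752 spots, of which 6834 were paired with a gene and 3918 with none. All 5606 gene identifiers matched the yeast reference annotation (assembly R64), which was used for names only. Spots of 1 gene were averaged. Of 1165 genes with several spots, 247 (21.2%) had a pair of spots whose median absolute difference over the arrays exceeded 0.5 on the log2 scale, and none of these is used below as an example except where that is said. Spots with a value numbered 7627 to 9765 per array, and 0.07% to 8.95% of the genes lacked a value. Signal over background is not analysed here, and the number of arrays limits the precision.

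Arrays were grouped by pulse and time into 7 windows before the data were examined, as were the comparisons, their tests, the gene lists, the naming rule and the alternatives not described below as added. The windows after 2 g/l were early (3 to 10 min, 4 arrays), middle (15 to 45 min, 4 arrays), late (90 to 150 min, 3 arrays) and last (180 to 240 min, 3 arrays). Those after 0.2 g/l were early (2 to 10 min, 5 arrays), middle (15 to 45 min, 4 arrays) and late (90 to 150 min, 3 arrays). The 5372 genes with at least 2 values in every window were tested with limma 3.58.1 in R 4.3.3, by lmFit with 7 window means and eBayes, and p values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. Each window mean was tested against 0, windows were compared between the pulses (2 g/l minus 0.2 g/l) and within a pulse (middle minus early, late minus middle), the difference between pulses of the last of these was tested, and a moderated F test took all windows of a pulse together. All tests were two-sided. Values are given as the mean log2 ratio ± SD over the arrays of a window. The SD is a spread between time points of 1 culture, so real change within a window adds to it, and the p values refer to that spread and not to replicate cultures. The dose and the culture cannot be told apart.

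Sets were tested with cameraPR on the moderated statistics, for 29 lists in 12 comparisons, adjusted over all 348 tests. This was done with a preset correlation of 0.01, and again with a correlation estimated from the residuals around the window means. A change within a window that the members of a list share adds to the estimated correlation. A list shift is the mean of its members minus the mean of all other genes. The lists were galactose use, hexose transport, gluconeogenesis and the glyoxylate cycle, glycolysis and ethanol fermentation, the TCA cycle, the respiratory chain and ATP synthase, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation initiation and elongation, the general stress response, trehalose and glycogen, chaperones of the heat shock factor, the proteasome, fatty acid oxidation and the peroxisome, amino acid biosynthesis, methionine and sulfate assimilation, purine and one-carbon metabolism, nitrogen catabolite repression, the phosphate response, the iron response, ergosterol biosynthesis, the G1 to S, G2 to M and M to G1 phases of the cell cycle, histones, mating and haploid cell type, and meiosis and sporulation. They were written from general knowledge of yeast and not chosen on these samples. PGM2 stands in 2 of them (galactose use, trehalose and glycogen), as does FAR1 (M to G1, mating). Member counts are given over all genes tested and adjusted over the list alone.

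Named genes are, per comparison, the 6 highest and 6 lowest estimates among called genes with the same sign on every array of the window (for differences, with arrays that do not overlap), all measured members of the lists for galactose use, hexose transport and gluconeogenesis, and up to 4 called members of each other list with the largest absolute estimate. Examples were drawn from these, with preference for genes called without each single array. Data preparation used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.

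The fit was tested on simulated data with the same 5372 genes and the missing values of these arrays, with 50 changed genes per fold size. These data held no error of the t=0 sample, so the numbers of unchanged genes called do not cover it. A simulation with such an error is given at the end of the results. For the middle window after 2 g/l it recovered 64% of genes changed 1.5-fold, 92% of those changed 2-fold and 98% of those changed 4-fold, with 7 unchanged genes called. For the late window after 0.2 g/l these shares were 42%, 88% and 96%, with 12 unchanged genes called, and for the difference between pulses in the middle window they were 26%, 54% and 94%, with 4 unchanged genes called.

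The alternatives chosen with the design were centring each array on its median, quantile normalization between arrays, genes with a value on all arrays (4028), genes with at least 1 value per window, a fit of only the windows compared, a fold minimum of 2, array weights, robust eBayes, 1 spot per gene, each array left out in turn, the matched time as a block (an approximation in limma where values are missing), and a natural cubic spline in the log of time with 4 degrees of freedom. Alternatives added after the data were seen were leaving out genes whose spots disagree, leaving out the 4 arrays lacking over 6% of the genes (2 g/l at 10 min, and 0.2 g/l at 15, 30 and 45 min), a middle window of 15 and 20 min or of 30 and 45 min only, the difference from the last window of the same pulse, and quantile normalization for the list shifts. Spots without a gene were left out of the comparisons, since the table gives them no identity. The raw intensities and images are not used here.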

Results

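The series followed how gene expression in galactose chemostats of yeast changed after a passing dose of glucose, as log2 ratios of each time after the pulse to the culture at t=0. There were 14 arrays after 2 g/l glucose, with 4 in the early, 4 in the middle, 3 in the late and 3 in the last window. There were 12 arrays after 0.2 g/l, with 5 in the early, 4 in the middle and 3 in the late window. Between 7627 and 9765 spots (median 8959) had a value per array, which gave 5104 to 5602 genes. The SD of all genes on an array ranged from 0.415 to 1.026, and the correlation of duplicate spots, across genes, from 0.24 to 0.724. The arrays least like the mean of their own window across genes were those of 0.2 g/l at 45 min (r = 0.123), 30 min (r = 0.365) and 90 min (r = 0.443).

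The galactose genes, which encode the permease (GAL2), the enzymes of galactose breakdown (GAL1, GAL7, GAL10) and their regulators, fell deeply after 2 g/l glucose. In the early window GAL2 had already reached -2.69 ± 1.30 (SD, n = 4, adjusted p = 0.00058), while GAL1 was at -0.30 ± 0.56 (adjusted p = 0.484). In the middle window GAL2 was at -4.03 ± 0.13 (SD, n = 4, adjusted p = 4.43e-06), GAL10 at -3.54 ± 0.12 (adjusted p = 9.51e-07) and GAL1 at -3.00 ± 0.53 (adjusted p = 7.82e-07). The inhibitor of the Gal4 activator, GAL80, was at -1.32 ± 0.18, and PGM2, for phosphoglucomutase, at -3.03 ± 0.20. All 9 members of the galactose list were lower in the middle window, and 9 adjusted over the list alone. In the early window 8 were lower, and 8 adjusted over the list alone, but 2 of these calls rested on single arrays: GAL7 lost its call without the array of 7 min (adjusted p = 0.0825) or 10 min (0.269), and GAL10 without 7 min (0.0769) or 10 min (0.249). As a set the list was lower in both windows with the preset correlation (adjusted p = 0.00017 and 5.76e-10), but adjusted p = 0.419 and adjusted p = 0.11 with an estimated correlation.

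The galactose genes came back near their t=0 level later. GAL1 was at -2.17 at 90 min, -0.72 at 120 min and 0.14 at 150 min after 2 g/l. In the late window limma called 0 of the 9 list members, with 5 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone, and in the last window 0, with 0 at an unadjusted p under 0.05. The list as a set was lower in the late window (adjusted p = 0.00986, but adjusted p = 0.564 with an estimated correlation), and this ended without the array of 90 min (adjusted p = 0.12). After 0.2 g/l, GAL2 fell to -1.93 ± 1.16 in the early window (SD, n = 5, adjusted p = 0.00334) and GAL80 to -0.60 ± 0.32, and 5 members of the list were lower there, with 6 adjusted over the list alone (set adjusted p = 0.00133, but adjusted p = 0.466 with an estimated correlation). Among these, GAL7 lost its call without the array of 6 min (adjusted p = 0.0965), 8 min (0.137) or 10 min (0.225) and GAL3 without 10 min (0.0557). GAL2 was at -2.80 at 15 min and at 0.37 by 30 min. In the middle window after 0.2 g/l GAL2 was at -0.76 ± 1.5 (SD, n = 4, adjusted p = 0.237). The 2 members that were lower there, GCY1 (-1.17 ± 1.03) and GAL3 (-0.89 ± 0.86), lost their calls without the array of 15 min (adjusted p = 0.0779 and 0.211) or 20 min (0.0504 and 0.103), and GAL3 also without 30 min (0.0591). In the late window 0 members were called by limma, with 0 at an unadjusted p under 0.05.

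**Figure D1:**
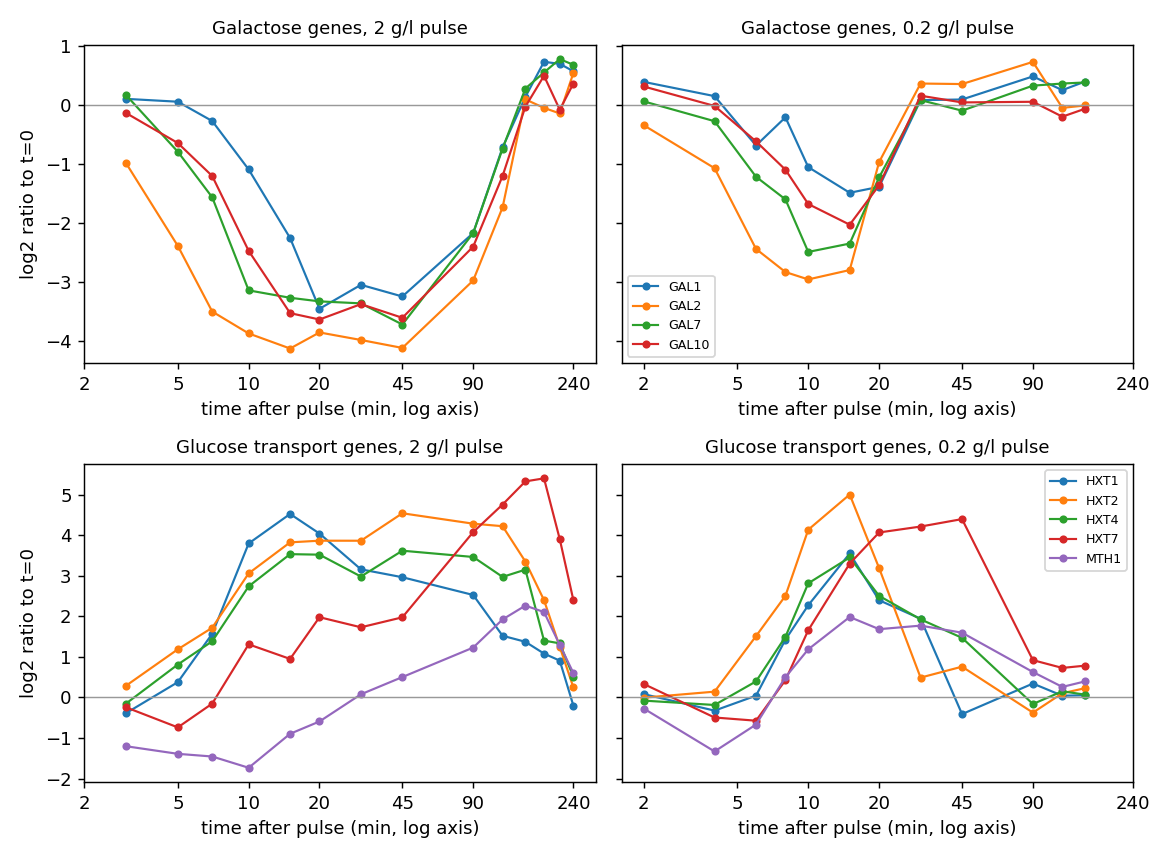
Log2 ratio to t=0 against time after the pulse (min, log axis) for 4 galactose genes and 5 glucose transport genes, 1 point per array, with the 2 g/l pulse on the left and the 0.2 g/l pulse on the right. GAL2 stayed near -4 from 10 to 45 min after 2 g/l (-3.88 and -4.12), while after 0.2 g/l it was at 0.37 by 30 min.

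Some genes for glucose transport rose steeply at different times, while most of the list was lower at first. HXT1, for the low-affinity transporter, and HXT2 and HXT4, for transporters of higher affinity, were at 3.68 ± 0.74, 4.03 ± 0.35 and 3.42 ± 0.29 in the middle window after 2 g/l (SD, n = 4, adjusted p = 2.39e-05, 2.75e-05 and 2.01e-06). HXT7, for a high-affinity transporter whose near-identical neighbour HXT6 was not measured, rose later, from 1.66 ± 0.49 in the middle window to 4.73 ± 0.63 in the late window (SD, n = 3, adjusted p = 1.14e-07) and 3.91 ± 1.5 in the last (adjusted p = 2.2e-05). MTH1, which encodes a corepressor of the HXT genes, fell to -1.45 ± 0.22 in the early window and rose to 1.81 ± 0.53 in the late window (SD, n = 3), while STD1, its paralog, rose to 1.96 ± 0.78 (SD, n = 4) in the early window. After 0.2 g/l HXT7 was at 4.00 ± 0.48 (SD, n = 4, adjusted p = 4.22e-07), HXT4 at 2.34 ± 0.86 and MTH1 at 1.76 ± 0.17 in the middle window, and HXT7 was back at 0.81 ± 0.10 (SD, n = 3, adjusted p = 0.282) in the late window. HXT2 reached 5.01 at 15 min after 0.2 g/l and was at 0.49 at 30 min, and its middle window call (2.36 ± 2.14) ended without the 15 min array (adjusted p = 0.0728). Of the 18 hexose transport genes measured, 4 were higher and 11 lower in the early window after 2 g/l (5 and 12 adjusted over the list alone), with HXT13 at -2.37 ± 1.24 and HXT17 at -2.13 ± 1.03 (SD, n = 4). The set was lower there (adjusted p = 0.0459, but adjusted p = 0.286 with an estimated correlation), and this ended without the array of 3 min (adjusted p = 0.076) or 7 min (0.0647).

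In the first 10 min both pulses raised genes for making ribosomes. After 2 g/l, 2019 of 5372 genes were called, 904 higher and 1115 lower, and after 0.2 g/l 1600, 973 higher and 627 lower. NSR1, for the nucleolin homologue of yeast, was at 2.43 ± 0.96 after 2 g/l (SD, n = 4, adjusted p = 0.000363) and 2.16 ± 0.75 after 0.2 g/l (SD, n = 5, adjusted p = 0.000346). Of 85 ribosome biogenesis genes, 68 were higher and 1 lower after 2 g/l (71 and 1 adjusted over the list alone), and 67 and 1 after 0.2 g/l (71 and 1 alone). The median of the list was 1.09 in both. Of 131 cytosolic ribosomal protein genes, 87 were higher after 2 g/l (94 alone) and 69 after 0.2 g/l (82 alone), and of 19 RNA polymerase I and III genes 14 (15 alone) and 19 (19 alone). AQR1, for a multidrug transporter, was highest with 2.71 ± 1.14 and 3.26 ± 0.90, and VID24, for a factor in the degradation of gluconeogenic enzymes, was at 2.23 ± 0.37 and 2.35 ± 0.45. AAH1, for adenine deaminase, was at 2.09 ± 0.64 and 2.08 ± 0.77. The lowest included ISF1 (-3.68 ± 1.27 and -2.88 ± 0.58) and TMA10 (-2.70 ± 0.41 and -2.70 ± 0.38), and MPC3, for a subunit of the mitochondrial pyruvate carrier, at -2.92 ± 0.78 after 0.2 g/l. The general stress list had 23 of 38 members lower after 2 g/l (24 alone) and 9 after 0.2 g/l (9 alone). The balance after 2 g/l turned to 534 higher and 343 lower with only this window in the fit, to 771 and 729 among genes with a value on all arrays and to 886 and 814 without the 4 arrays with many missing values. That after 0.2 g/l was 1080 and 1037 with quantile normalization and turned to 133 and 162 with a minimum of 2-fold. The count after 2 g/l was 1157 without the array of 10 min, and the count after 0.2 g/l was 1043 without 8 min and 996 without 10 min.

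With the preset correlation the ribosome biogenesis set was higher early after both pulses (adjusted p = 5.96e-20 and 4.64e-23), but adjusted p = 0.37 and adjusted p = 0.312 with an estimated correlation. Cytosolic ribosomal proteins were higher (adjusted p = 2.62e-20 and 3.94e-11, but adjusted p = 0.429 and adjusted p = 0.576 with an estimated correlation), and the stress list was lower (adjusted p = 1.51e-08 and 0.00152, but adjusted p = 0.429 and adjusted p = 0.664 with an estimated correlation). Amino acid biosynthesis, with 38 of 57 members higher and 1 lower after 0.2 g/l (41 and 1 alone), held with both correlations in that window (adjusted p = 7.64e-12 and 0.0484). ILV3, for a step of valine and isoleucine synthesis, was at 1.25 ± 0.22 (SD, n = 5). The iron response list also held there, with 16 of 19 members lower (17 alone), a median of -1.25 and adjusted p = 2.74e-27 (0.000119 with an estimated correlation). TIS11, for a factor that destabilizes mRNAs when iron is low, was at -2.44 ± 0.30 (SD, n = 5, adjusted p = 3.4e-10) and the siderophore transporter SIT1 at -2.01 ± 0.42. In the early window after 2 g/l 2 members of this list were higher and 2 lower. Of all 348 set tests, 181 passed with the preset correlation and 17 with an estimated one. These 17 were the iron response in 8 comparisons (all windows of both pulses except early and middle after 2 g/l, the differences between pulses early and late, and middle to late after 2 g/l), glycolysis in 3 (late after 2 g/l, the late difference, middle to late after 0.2 g/l), the proteasome in 2 (last after 2 g/l, late after 0.2 g/l), amino acid biosynthesis in 2 (middle after 2 g/l, early after 0.2 g/l), and mitochondrial ribosomal proteins and chaperones in middle to late after 2 g/l. Of these, 6 were windows before the last of their pulse. Against that last window, where an offset of the t=0 sample cancels, the iron response late after 2 g/l held (adjusted p = 6.67e-05 with an estimated correlation). The iron response early and middle after 0.2 g/l gave adjusted p = 0.484 and 0.364 with an estimated correlation, amino acid biosynthesis middle after 2 g/l and early after 0.2 g/l gave 0.257 and 0.607, and glycolysis late after 2 g/l gave 0.506.

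From 15 to 45 min after 2 g/l the genes of respiration and of growth on poor carbon sources were low and those of fermentation high. PDC1, for the main pyruvate decarboxylase, was at 2.52 ± 0.12 (SD, n = 4), and PFK27, which makes the activator of glycolysis fructose 2,6-bisphosphate, at 2.68 ± 0.19. GPP1, for glycerol phosphatase, was at 2.60 ± 0.49 (adjusted p = 1.08e-06), and ARI1, for an aldehyde reductase, at 3.59 ± 0.27 (adjusted p = 1.44e-06). FBP1 and MLS1, for fructose bisphosphatase and malate synthase, were at -2.41 ± 0.12 and -2.69 ± 0.21. Of 19 gluconeogenesis and glyoxylate genes 16 were lower (16 alone), of 18 TCA cycle genes 17 (17 alone, CIT1 at -2.23 ± 0.72), of 32 respiratory chain genes 22 (25 alone), of 63 mitochondrial ribosomal protein genes 34 lower and 1 higher (35 and 1 alone), and of 38 stress genes 34 (35 alone, DDR2 at -3.02 ± 0.47 and HSP26 at -2.56 ± 0.27). Of 21 trehalose and glycogen genes 17 were lower, with TSL1 of the trehalose synthase complex at -2.13 ± 0.56. Of 20 chaperone genes 14 were lower (1 higher and 15 lower alone), and of 18 fatty acid oxidation genes 11 (11 alone, FOX2 at -1.99 ± 0.27). In contrast 126 of 131 cytosolic ribosomal protein genes were higher (126 alone) with a median of 1.00, 73 of 85 ribosome biogenesis genes (78 alone), 25 of 31 translation genes (25 alone) and 19 of 20 purine genes (19 alone). Amino acid biosynthesis had 38 members higher and 3 lower (39 and 3 alone). In total 2354 genes were called, 1165 higher and 1189 lower.

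The cytosolic ribosomal proteins gave adjusted p = 1.45e-40 as a set in that window, the TCA cycle 8.71e-09, the respiratory chain 1.08e-06 and the stress list 1.52e-19, but adjusted p = 0.213, adjusted p = 0.263, adjusted p = 0.352 and adjusted p = 0.16 with an estimated correlation. Gluconeogenesis (3.11e-07), mitochondrial ribosomal proteins (3.18e-07) and trehalose and glycogen (2.13e-07) gave adjusted p = 0.312, adjusted p = 0.419 and adjusted p = 0.352 with an estimated correlation. Chaperones (6.06e-05), fatty acid oxidation (9.4e-05), ribosome biogenesis (1.71e-19), translation (1.1e-08) and purine metabolism (2.61e-08) gave adjusted p = 0.145, 0.455, 0.38, 0.275 and 0.257 with an estimated correlation. Amino acid biosynthesis was higher with both correlations (adjusted p = 4.96e-12 and 0.047). Glycolysis had 10 of 19 members higher and 2 lower (12 and 2 alone), with GLK1, for glucokinase, at -2.22 ± 0.47 (set adjusted p = 3.62e-05, but adjusted p = 0.201 with an estimated correlation). Against the last window of the pulse its shift turned to -0.005 (adjusted p = 0.416).

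From 90 min after 2 g/l fermentation genes were still high while iron genes were at their lowest. CDC19, for pyruvate kinase, was at 1.44 ± 0.61 in the late window (SD, n = 3), PDC1 at 1.73 ± 0.43 and ENO2 at 1.25 ± 0.42, and 11 of 19 glycolysis genes were higher (14 alone), with adjusted p = 1.9e-09 as a set (0.0256 with an estimated correlation). Against the last window this call ended (shift 0.211, adjusted p = 0.0532). FIT2 and FIT3, for cell wall proteins that retain siderophore iron, were at -4.22 ± 0.46 and -2.72 ± 0.66 (adjusted p = 1.21e-09 and 1.2e-09), the reductase FRE3 was at -2.93 ± 0.15 and SIT1 at -2.61 ± 0.67. Of 19 iron genes 15 were lower (17 alone), with a median of -2.12 and adjusted p = 5.77e-63 (3.43e-11 with an estimated correlation). FBP1 was at -2.56 ± 0.07 (adjusted p = 3.37e-05) and PCK1, for phosphoenolpyruvate carboxykinase, at -1.63 ± 0.12, and 76 cytosolic ribosomal protein genes were higher (96 alone, set adjusted p = 2.68e-25, but adjusted p = 0.371 with an estimated correlation). Of 10 histone genes 7 were higher (7 alone, set adjusted p = 1.49e-05, but adjusted p = 0.16 with an estimated correlation). HHF1 was at 0.93 ± 0.15, but it was higher on every array and already at 0.755 at 3 min. Limma called 0 ribosome biogenesis genes, with 13 at an unadjusted p under 0.05, while the set was higher (median 0.37, adjusted p = 0.00405, but adjusted p = 0.808 with an estimated correlation), which ended without the array of 90 min (adjusted p = 0.0829). The window had 781 calls, 485 higher and 296 lower (714 and 729 with quantile normalization). The count was 288 without the array of 90 min or 368 without that of 120 min. The balance turned to 47 higher and 107 lower with a minimum of 2-fold, and to 11 and 56 against the last window.

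In the last window, 180 to 240 min after 2 g/l, 19 of 31 proteasome genes were higher (21 higher and 1 lower alone), with a median of 0.52 and adjusted p = 2.54e-17 (0.00538 with an estimated correlation). PRE7 and SCL1, for subunits of the core particle, were at 0.86 ± 0.27 and 0.69 ± 0.15 (SD, n = 3). AHP1, for a peroxiredoxin, was at 1.61 ± 0.59 (adjusted p = 4.88e-05). Of the mitochondrial ribosomal protein genes 21 were higher and 2 lower (31 and 2 alone, set adjusted p = 1.8e-09, but adjusted p = 0.304 with an estimated correlation), with MRPL37 at 1.18 ± 0.48. Of the iron genes 11 were lower (13 alone, adjusted p = 1.91e-14, and 0.0146 with an estimated correlation), with FRE3 at -1.98 ± 0.32. There were 450 calls, 320 higher and 130 lower (566 and 636 with quantile normalization). The count was 299 without the array of 180 min, 50 without that of 210 min, and 71 with only this window in the fit. The balance turned to 29 higher and 42 lower in that fit, and to 17 and 34 with a minimum of 2-fold.

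**Figure D2:**
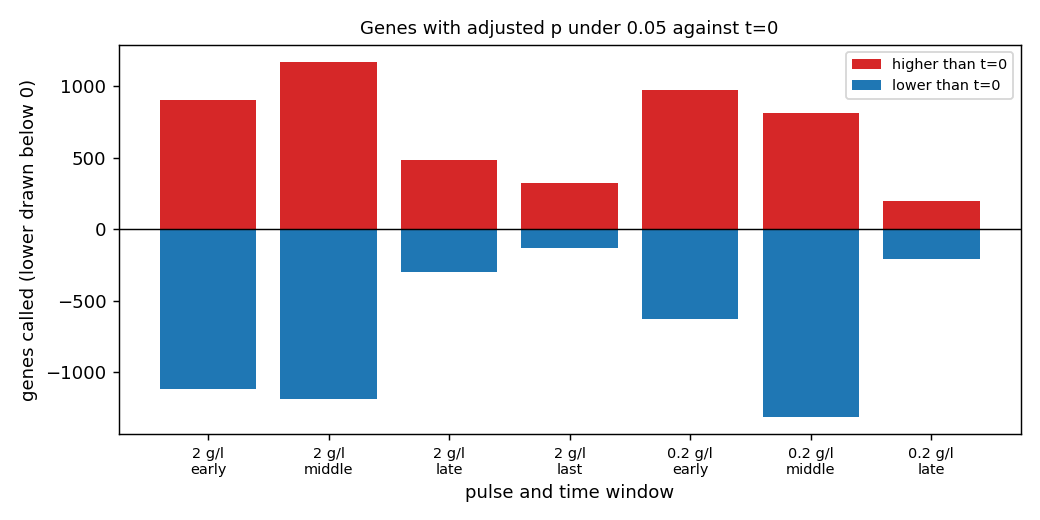
Number of genes called against t=0 at an adjusted p under 0.05 in each of the 7 windows, with bars above 0 for higher and below 0 for lower genes. After 2 g/l the counts were 2019, 2354, 781 and 450, and after 0.2 g/l 1600, 2120 and 405, where quantile normalization put the early window (2117) above the middle one (1453).

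Between 15 and 45 min after 0.2 g/l, genes for gluconeogenesis were low and ribosomal protein genes high, as after 2 g/l. PCK1 was at -1.53 ± 0.40 (SD, n = 4), FBP1 at -1.76 ± 0.67 and ACS1, for acetyl-CoA synthetase, at -1.87 ± 0.32, and 16 of 19 gluconeogenesis genes were lower (16 alone). HXK2, for the main hexokinase, was at 0.99 ± 0.09, and 12 of 19 glycolysis genes were higher (12 alone). Of the cytosolic ribosomal protein genes 125 were higher and 4 lower (126 and 4 alone), of those of ribosome biogenesis 26 and 6 (25 and 6 alone). FIT2 was at -3.84 ± 0.22 (adjusted p = 9.04e-10), and 15 iron genes were lower (16 alone, adjusted p = 1.39e-19, and 0.00264 with an estimated correlation). Ribosomal proteins, gluconeogenesis and glycolysis gave adjusted p = 1.32e-51, 1.11e-07 and 2.02e-07 as sets, but adjusted p = 0.145, 0.304 and 0.0769 with an estimated correlation. Of 16 phosphate response genes 6 were lower (6 alone, set adjusted p = 0.045, but adjusted p = 0.576 with an estimated correlation), and this set call ended without the array of 20 min (adjusted p = 0.0682), 30 min (0.0766) or 45 min (0.169), and against the late window of the pulse (shift -0.077, adjusted p = 0.872). In all 2120 genes were called, 811 higher and 1309 lower (784 and 669 with quantile normalization). The balance was 67 higher and 532 lower with a minimum of 2-fold. It was 1090 and 1033 with 15 and 20 min only as the middle window, and 187 and 761 with 30 and 45 min only. The median of all genes in this window was -0.126. With only this window in the fit limma called 2 genes, with 1284 at an unadjusted p under 0.05. Without the 4 arrays with many missing values, which leaves 1 array in this window, the count was 1196 (607 higher, 589 lower).

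In the late window after 0.2 g/l iron genes were still low and proteasome genes were high. Of 31 proteasome genes 14 were higher (20 higher and 1 lower alone, adjusted p = 4.71e-12, and 0.0378 with an estimated correlation), with SCL1 at 0.75 ± 0.13 (SD, n = 3). Of the iron genes 10 were lower (12 alone, adjusted p = 2.05e-18, and 0.0038 with an estimated correlation), with FIT3 at -2.10 ± 0.06. SNZ1, for vitamin B6 synthesis, was at 0.83 ± 0.21 (adjusted p = 0.00172), while ATP10, for an assembly factor of ATP synthase, was at -2.66 ± 1.57 (adjusted p = 0.000845). Of the amino acid genes 12 were higher and 1 lower (20 and 2 alone, set adjusted p = 4.52e-07, but adjusted p = 0.213 with an estimated correlation). There were 405 calls, 194 higher and 211 lower (664 and 635 with quantile normalization, 149 and 258 with centring). This balance also changed to 1 higher and 102 lower with a minimum of 2-fold, and to 172 higher and 84 lower among genes with a value on all arrays. The count was 161 without the array of 90 min, 96 without that of 150 min, and 0 with only this window in the limma fit, where 1418 genes had an unadjusted p under 0.05.

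The larger and the smaller pulse were compared within each window. In the first 10 min 26 genes differed, 13 higher and 13 lower after 2 g/l, and 9 of the higher ones but none of the lower ones were members of the iron list. TIS11 was higher by 2.29 (adjusted p = 3.21e-06), and SIT1 and ENB1, for siderophore transporters, by 1.92 and 1.87 (adjusted p = 5.89e-05 for each). The iron list had 14 members higher when adjusted over the list alone, with adjusted p = 5.97e-54 as a set (1.25e-09 with an estimated correlation). Stress genes had 1 member lower (5 alone, set adjusted p = 8.87e-06, but adjusted p = 0.538 with an estimated correlation). The even split did not hold: 12 were higher and 0 lower with only these windows in the limma fit, which had 684 genes at an unadjusted p under 0.05, 13 and 4 without the 4 arrays with many missing values, and 58 and 185 with array weights. The count was 156 without the 2 g/l array of 5 min (19 higher, 137 lower), 13 without that of 7 min (10 and 3), 17 without that of 10 min (12 and 5) and 15 without the 0.2 g/l array of 6 min (10 and 5).

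In the middle window the galactose genes were lower after the larger pulse, GAL2 by 3.27 (adjusted p = 0.00538), GAL10 by 2.75 (0.00269) and GAL1 by 2.33 (0.00249) on the log2 scale, and 7 of the 9 members were called lower (8 alone). HXT7 and MTH1 were lower by 2.34 and 1.99, and PDC1 was higher by 1.43. Amino acid genes were higher after the larger pulse (27 of 57, 34 alone, with HIS1 by 2.10), as were ribosome biogenesis (18 of 85, 31 alone) and iron genes (11 of 19, 13 alone, with FIT2 by 2.36). Respiratory chain genes were lower (14 of 32, 21 alone, with CYC1 by 1.31), as were those of the TCA cycle (9 of 18, 12 alone) and the stress list (11 of 38, 1 higher and 12 lower alone). The galactose, respiratory chain, TCA and stress sets gave adjusted p = 2.72e-08, 3.56e-12, 8.79e-08 and 2.14e-08, but adjusted p = 0.16, 0.145, 0.304 and 0.429 with an estimated correlation. The amino acid, ribosome biogenesis and iron sets gave adjusted p = 2.07e-11, 2.18e-09 and 2.36e-09, but adjusted p = 0.0561, 0.569 and 0.109 with an estimated correlation. There were 794 calls, 458 higher and 336 lower (191 and 361 with quantile normalization), and the median of all genes was 0.127. With the matched time as a block the count was 378, with 177 higher and 201 lower. With only these windows in the fit limma called 0 genes, with 1194 at an unadjusted p under 0.05. Without the 4 arrays with many missing values the count was 309, without the 2 g/l array of 15 min 492 and without that of 20 min 381.

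In the late window HXT7 and HXT4 were higher after the larger pulse by 3.92 and 3.18 (adjusted p = 0.00127 and 0.00924), PDC1 by 2.17 and CDC19 by 1.51, and 8 of 19 glycolysis genes were higher (10 alone, adjusted p = 1.44e-10, and 0.0146 with an estimated correlation). FBP1 was lower by 3.09, PCK1 by 2.10 and HSP26 by 2.74 on the log2 scale. Gluconeogenesis had 6 members lower (9 alone, set adjusted p = 4.8e-09, but adjusted p = 0.242 with an estimated correlation) and the stress list 8 (12 alone, set adjusted p = 7.39e-13, but adjusted p = 0.286 with an estimated correlation). Iron genes were now lower after the larger pulse, 10 of 19 (13 alone, adjusted p = 1.71e-19, and 0.00264 with an estimated correlation). There were 163 calls, 61 higher and 102 lower. With the matched time as a block the count was 32 (10 higher, 22 lower), and with quantile normalization 654 (249 higher, 405 lower). The count was 60 without the 2 g/l array of 90 min, 59 without that of 120 min and 59 without the 0.2 g/l array of 150 min.

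**Figure D3:**
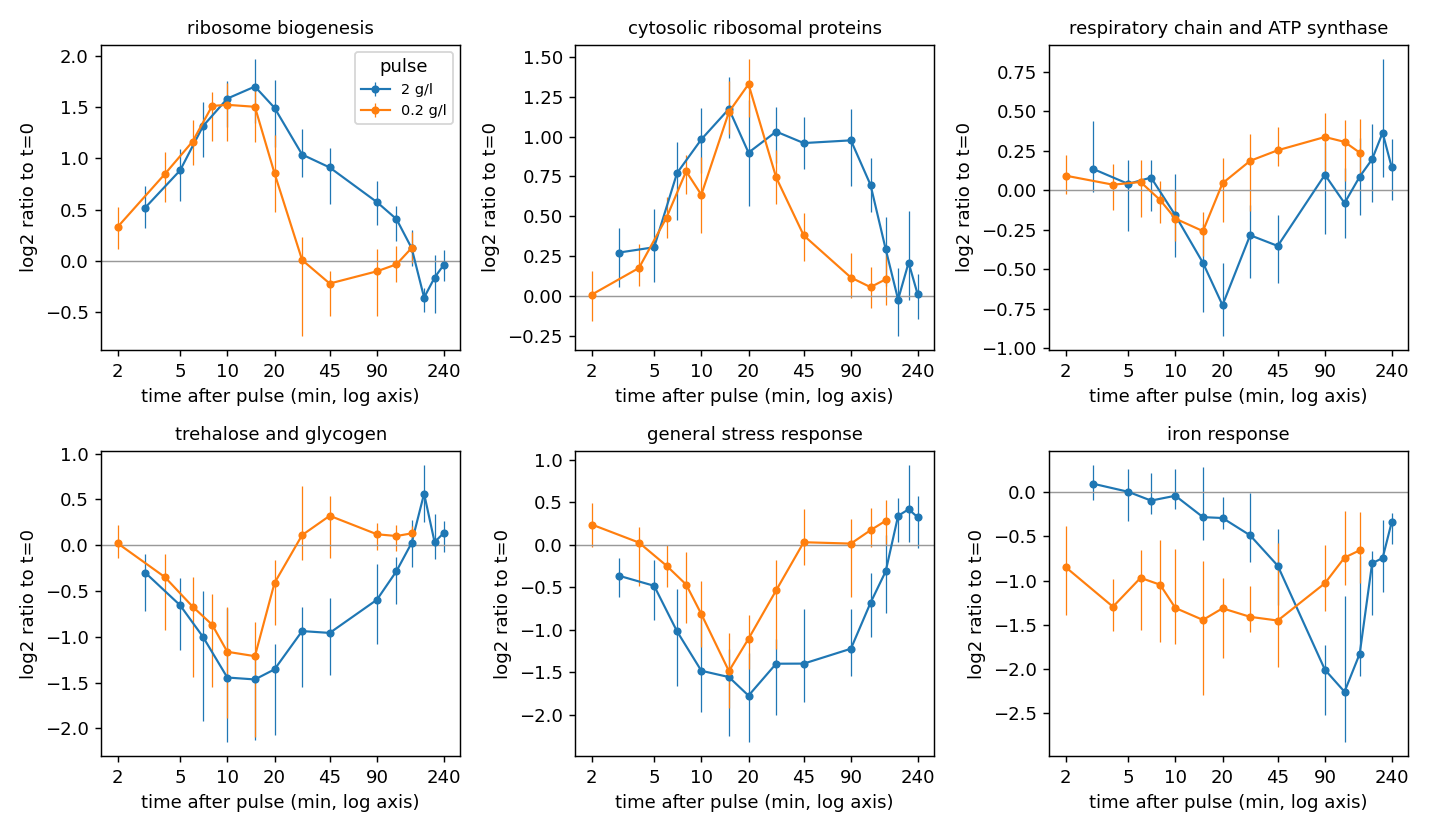
Median log2 ratio to t=0 of 6 gene lists against time after the pulse (min, log axis), with bars from the first to the third quartile of the members and 1 point per array for each pulse. The iron response was at -0.85 at 2 min after 0.2 g/l and near 0 at 3 to 10 min after 2 g/l (0.10 to -0.09), with its lowest median, -2.26, at 120 min after 2 g/l.

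From the early to the middle window after 2 g/l, GAL1 fell by 2.71 (adjusted p = 0.00431) and DDR2, for a stress protein, by 2.11 on the log2 scale, and CDC19 rose by 1.30 (adjusted p = 0.011). There were 113 calls, 27 higher and 86 lower (33 and 59 with quantile normalization). The count was 66 without the array of 3 min, 75 without 7 min, 32 without 20 min, 48 without 30 min and 56 without 45 min. From the middle to the late window, the question was which genes came back. HXT7 rose by 3.07 (adjusted p = 0.00441) and GAL80 by 1.22 (adjusted p = 0.00542), while GAL1 rose by 2.09 (adjusted p = 0.0139), a call that ended without the array of 20 min (adjusted p = 0.0573), 120 min (0.0707) or 150 min (0.153). Of 63 mitochondrial ribosomal protein genes 28 rose (50 alone, with 1 lower alone, adjusted p = 1.66e-29, and 0.0133 with an estimated correlation), MRPL39 by 1.38. Of 20 chaperone genes 11 rose (14 alone, adjusted p = 3.1e-12, and 0.000922 with an estimated correlation), with AHA1, for an activator of Hsp90, by 1.21. FIT2 fell by 2.75 on the log2 scale, with 13 iron genes lower (16 alone, adjusted p = 9.74e-40, and 5.66e-07 with an estimated correlation). Galactose genes had 5 members higher (8 alone, set adjusted p = 8.73e-08, but adjusted p = 0.19 with an estimated correlation). There were 229 calls, 186 higher and 43 lower (156 and 71 with quantile normalization). The count was 134 without the array of 15 min, 95 without 20 min, 90 without 120 min and 51 without 150 min.

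Within the 0.2 g/l pulse, HXT7 rose by 3.73 from the early to the middle window (adjusted p = 0.000393), MTH1 by 1.88 and HXK2 by 1.28, and PCK1 fell by 1.45 on the log2 scale. There were 334 calls, 61 higher and 273 lower (171 and 214 with quantile normalization, 94 and 214 with centring), and the median of all genes was -0.137. The count was 190 without the array of 4 min, 129 without 6 min, 215 without 8 min, 166 without 30 min and 844 without 45 min. From the middle to the late window HXT7 fell by 3.19 on the log2 scale and PCK1 rose by 2.01 (adjusted p = 0.0073 for each), but both calls ended without the array of 150 min (adjusted p = 0.0507 for each). Glycolysis genes had 4 members lower (9 alone, adjusted p = 1.86e-10, and 0.0146 with an estimated correlation), and 16 cytosolic ribosomal protein genes were lower (1 higher and 115 lower alone, set adjusted p = 4.23e-58, but adjusted p = 0.11 with an estimated correlation). Hexose transport genes were lower as a set (shift -0.68, adjusted p = 0.0254, but adjusted p = 0.213 with an estimated correlation) with a median of -0.01, and this ended without the array of 30 min (adjusted p = 0.114), 45 min (0.0561) or 150 min (0.056). There were 102 calls, 68 higher and 34 lower (163 and 177 with quantile normalization, 59 and 67 with centring), and the median of all genes was 0.139. The count was 43 without the array of 15 min, 41 without 20 min, 829 without 45 min, 58 without 90 min, 35 without 120 min and 1 without 150 min.

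The change from the middle to the late window differed between the pulses for HXT7, by 6.25 (adjusted p = 0.000106), for MTH1 by 3.37 and for HXK2 by 1.97, all higher after 2 g/l. It was lower after 2 g/l for FIT2 (-4.13, adjusted p = 0.000106), ENB1 (-3.65, adjusted p = 2.05e-05) and PCK1 (-2.70). There were 28 calls, 7 higher and 21 lower (22 and 36 with quantile normalization), and 81 without the 0.2 g/l array of 45 min. With the matched time as a block the count was 11 (2 higher, 9 lower). Over all windows of a pulse 3141 genes were called after 2 g/l and 2807 after 0.2 g/l. A spline in time, which tests for change over the course and not against t=0, gave 1874 and 1014. Across genes, which are not independent replicates, the profiles of both pulses at the same time had Pearson r = 0.673 at 10 min, 0.680 at 15 min, 0.565 at 20 min, 0.219 at 30 min, -0.014 at 45 min, 0.263 at 90 min, 0.306 at 120 min and 0.305 at 150 min. Spearman rho was 0.704, 0.742, 0.558, 0.331, 0.014, 0.290, 0.320 and 0.342. Values simulated with nothing in common but 1 shared t=0 sample gave r = 0.5. That value was fixed in advance, because the simulated t=0 sample had the same spread as each array. The spread of the real t=0 samples was not measured, so 0.5 is no reference for the correlations above.

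Lists not described above gave the following. In the middle window after 2 g/l, methionine and sulfate genes had 14 of 25 members higher (14 higher and 1 lower alone, set adjusted p = 0.000809, but adjusted p = 0.429 with an estimated correlation), with STR3 at 1.73 ± 0.66. Nitrogen catabolite repression had 7 of 22 higher and 3 lower (set adjusted p = 0.461), ergosterol biosynthesis 5 of 22 higher and 1 lower (0.126), and mating and haploid cell type 8 of 23 higher and 2 lower (0.154), with SST2 at 1.18 ± 0.13 (SD, n = 4). Of the cell cycle lists G1 to S had 1 of 30 higher and 7 lower (0.256), with RNR1, for ribonucleotide reductase, at -1.45 ± 0.21. G2 to M had 4 of 20 higher and 2 lower (0.711) and M to G1 4 of 23 higher and 3 lower (0.805). RNR1 was lower on every array and already at -1.916 on the first array of each pulse, so its value is not particular to this window. Meiosis and sporulation genes were lower in the early window after 2 g/l, with 11 of 23 lower (12 alone, set adjusted p = 0.00032, but adjusted p = 0.429 with an estimated correlation) and MEK1 at -1.30 ± 0.57. Against the last window of the pulse this set call ended (shift -0.376, adjusted p = 0.0979).

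Every test of a window against 0 leaves out the spread of the t=0 sample. In 20 simulated data sets without any change, where each pulse shared 1 t=0 sample with the spread of these arrays, on average 1232.4 genes were called in the early and 1231.8 in the middle window after 2 g/l, against 2019 and 2354 observed, and 834.2 and 849.8 in its late and last windows, against 781 and 450. After 0.2 g/l these averages were 1541.2, 1156.2 and 826.9, against 1600, 2120 and 405. The differences between pulses carried both simulated t=0 samples, which were drawn separately, and gave 1363.2, 1190 and 823.3, against 26, 794 and 163. Comparisons of windows within a pulse, in which the t=0 sample cancels, gave at most 0.1. The simulated spread was that around the window means, to which real change within a window adds. The averages exceeded the observed counts late and last after 2 g/l, late after 0.2 g/l and in each difference between pulses. An error of that size goes against those counts, for the differences only if each pulse had its own t=0 sample. The error of a sample shared by both pulses would cancel there, and whether they shared it is not known. A smaller error was not simulated, so how many calls come from the t=0 sample stays open.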

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

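The tests on the iron genes and those on the middle window other than the splits of the arrays were chosen only after the result was seen.

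The iron response genes were low from the first array after 0.2 g/l, and this set the pulses apart. The list was higher after 2 g/l in the early window by 1.204 relative to all other genes (adjusted p = 1.25e-09 with an estimated correlation), and lower in the late window by -1.024 (adjusted p = 0.00264). A response to glucose in both cultures within minutes is argued against by the arrays of 3 to 10 min after 2 g/l, where the lowest median of the list was -0.092. This holds only if the t=0 sample of the 2 g/l culture did not have low levels of iron genes, which would hide a fall and was not tested. A t=0 sample of the 0.2 g/l culture with high levels of iron genes would lower every array alike. In line with that, the median was already -0.849 at 2 min, 0.654 of the median of the later arrays (-1.298, range -1.455 to -0.657). Against the last window of that pulse, where such an offset cancels, the list was still lower early (-0.285, adjusted p = 0.0115) and in the middle (-0.341, adjusted p = 0.00166), but adjusted p = 0.484 and adjusted p = 0.364 with an estimated correlation, so whether an offset accounts for all of it stays open. A response of this culture alone within 2 min, or a difference in the medium, was not tested.

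The middle window differed between the pulses in 794 genes, with 148 as the highest count of the other 34 of 35 splits of the 8 arrays, and only the real split (1 of 35) gave as many. This does not exclude chance, since the splits ignore that both pulses have the same 4 times and cannot show the error of the t=0 samples. With the matched time as a block 378 genes differed (177 higher, 201 lower), and data simulated with separate t=0 errors and no change gave 1190 on average. The same simulation gave far more than observed in the early and late windows (1363.2 against 26 and 823.3 against 163), so separate errors of that size go against these data. Whether the pulses shared a t=0 sample, whose error would cancel in the difference, is not known. A smaller error was not simulated and stays open. Missing values are argued against as the only source, since 17.3% of the genes with a value on all arrays were called against 14.8% of all genes tested. Genes with all values have more data per window, which by itself raises their share, so a part played by missing values stays open. The balance was 362 higher and 334 lower among these genes, against 458 and 336 among all genes tested. The quality of the 4 arrays with many missing values stays open, since 309 genes were called without them, with 1 array left in the 0.2 g/l window. The array of 0.2 g/l at 45 min, the least like its window, is argued against as the only source by 887 genes called without it. For all genes together, an earlier return of the 0.2 g/l culture was not told apart from a difference in the response. GAL2 did return earlier after 0.2 g/l, by the values given above, but it is 1 gene. The array of 0.2 g/l at 45 min correlated best with 2 g/l at 180 min (r = 0.227, across genes), only 0.091 above its best match up to 45 min, and the genes are not independent replicates.

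In the early window 26 genes differed between the pulses. Of 100 splits of these arrays, 3 gave as many genes, with 39 as the highest count of the others, a share under 0.05. The splits do not cover an error of the t=0 samples. In the late window 163 genes differed, against 0 in the highest other of the 10 splits of the limma fit, 1 of 10 being the real one, which are too few for a share under 0.05. The glycolysis list was higher after 2 g/l in the late window by 0.715 (adjusted p = 0.0146 with an estimated correlation).

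The change from the middle to the late window differed between the pulses in 28 genes, and in 11 with the matched time as a block. Of 100 splits 7 gave at least 28 genes, with 467 as the highest, so chance cannot be excluded. What gave a count several times the real one was not tested. Within the 2 g/l pulse 113 genes changed from the early to the middle window (1 of 35 splits, highest other 4) and 229 from the middle to the late window (1 of 35 splits, highest other 16), so no other split gave as many. These arrays are consecutive times of 1 culture and not exchangeable replicates, so this does not exclude chance. With only the windows compared in the fit the counts were 25 and 742, and they fell to 32 for early to middle without the array of 20 min and to 51 for middle to late without that of 150 min. Within the 0.2 g/l pulse 334 genes changed from early to middle (5 of 100 splits, highest other 586) and 102 from middle to late (5 of 35 splits, highest other 1027). Chance cannot be excluded for either. These arrays too are consecutive times of 1 culture, so a split with more genes than the real one need not be chance. The count from middle to late depended on the times taken as middle, with 1012 genes for 15 and 20 min and 15 for 30 and 45 min. What gave the high counts of other splits was not tested.

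In 128 tests of a list median or a measure of array quality in a window, 4, all of list medians, had 1 array far from the others of its window, and chance gives about 1 in 20. The hexose transport list had a median of -0.11 at 2 min after 0.2 g/l, with -0.402 to -0.335 at its other early times. The nitrogen catabolite repression list was at 0.202 on the same array, with -0.408 to -0.32 at the others. The glycolysis list was at 0.403 at 10 min after 2 g/l, with 0.218 to 0.224 at the other early times, and the mitochondrial ribosomal proteins were at -0.164 at 10 min after 0.2 g/l, with -0.018 to 0.012 at the others. These arrays are times in a course, so a change with time also sets them apart.

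Spots without a gene name also gave signals. Of 1815 such spots tested, 573 were called in the middle window after 2 g/l, 276 higher and 297 lower. In every other window too more were lower than higher. After 2 g/l these were 585 and 178 early, 114 and 78 late and 179 and 35 last, and after 0.2 g/l 259 and 182 early, 651 and 192 in the middle and 298 and 27 late.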

How the results depend on the processing

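The fit against the last window of a pulse, the narrower middle windows, the omission of 4 arrays with many missing values or of genes whose spots disagree, and quantile normalization of list shifts were chosen only after the result was seen. Windows are written early, middle, late and last, e-m for early to middle and m-l for middle to late.

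Centring and genes with at least 1 value per window kept every count within 1.5 times, as did robust eBayes, 1 spot per gene and leaving out genes whose spots disagree. Genes with a value on all arrays did so except late after 0.2 g/l (256).

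Quantile normalization gave 1443 genes late and 1202 last after 2 g/l, 1299 late after 0.2 g/l, 41 and 654 for the early and late differences, 340 for m-l after 0.2 g/l and 58 for the difference in m-l. The cause was not tested. Under it 163 list calls held, 16 were lost, and 2 reversed: amino acid biosynthesis in m-l after 2 g/l (shift 0.022) and the iron response in m-l after 0.2 g/l (-0.142).

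With only the windows compared in the fit, 2 g/l gave 877 early, 1218 late and 71 last, and 0.2 g/l gave 2 in the middle and 0 late by limma, where 1284 and 1418 had an unadjusted p under 0.05. The differences gave 12 early and 0 in the middle (684 and 1194 unadjusted). E-m and m-l gave 25 and 742 after 2 g/l and 10 and 1 after 0.2 g/l. Fewer arrays leave fewer degrees of freedom, and counts moved both ways, with the cause otherwise not tested.

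A minimum of 2-fold, which by construction removes genes, left 530, 635, 154 and 51 after 2 g/l, 295, 599 and 103 after 0.2 g/l, and 17, 320 and 84 for the differences. It left 43 and 105 for e-m and m-l after 2 g/l, 178 for e-m after 0.2 g/l, and 949 and 787 over the courses.

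Array weights gave 2032 late and 758 last after 2 g/l, 2895 early and 1885 late after 0.2 g/l, and 243, 1221 and 1198 for the differences. They gave 391 and 1465 for e-m and m-l after 2 g/l, 1277 and 1659 after 0.2 g/l, 557 for the difference in m-l and 4244 over the 0.2 g/l course. The cause was not tested.

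Without the 4 arrays, which leaves 1 in the middle window after 0.2 g/l that is assumed to vary like the other groups, the counts were 1317 late and 811 last after 2 g/l, 1196 in the middle and 776 late after 0.2 g/l, and 17, 309 and 380 for the differences. They were 401 and 671 for e-m and m-l after 2 g/l and 274 for m-l after 0.2 g/l. The cause was not tested.

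A middle window of 30 and 45 min gave 1048 after 2 g/l, 948 after 0.2 g/l and 512 for their difference, 20 and 37 for e-m and m-l after 2 g/l, and 783 and 15 after 0.2 g/l. One of 15 and 20 min gave 345 for the difference, 694 for m-l after 2 g/l, 520 and 1012 for e-m and m-l after 0.2 g/l, and 56 for the difference in m-l. The cause was not tested.

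Against the last window of the pulse, in which an offset of the t=0 sample cancels, 629, 1488 and 67 genes differed early, middle and late after 2 g/l, and 203 and 102 early and middle after 0.2 g/l. Of 84 list calls 64 held. The 12 lost were gluconeogenesis, fatty acid oxidation, amino acid biosynthesis, histones and meiosis early after 2 g/l, histones in its middle window, glycolysis and meiosis in its late window, nitrogen catabolite repression, G1 to S and meiosis early after 0.2 g/l, and the phosphate response in its middle window. The 8 reversed were glycolysis (-0.268) and the proteasome (-0.232) early after 2 g/l, glycolysis (-0.005) and the iron response (0.364) in its middle window, mitochondrial ribosomal proteins (-0.049), the proteasome (-0.213) and M to G1 (0.026) in its late window, and the proteasome early after 0.2 g/l (-0.264). By construction a list that was still away from t=0 in the last window is moved by that amount.

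The matched time as a block gave 378 and 32 for the middle and late differences and 11 for the difference in m-l. The spline gave 1874 and 1014 over the courses. Only 17 list calls passed with an estimated correlation, to which a change within a window that list members share adds. The cause was not tested.

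With each array left out in turn, counts were 1157 to 1955 early, 1806 to 2174 in the middle, 288 to 548 late and 50 to 305 last after 2 g/l. After 0.2 g/l they were 996 to 1653, 1474 to 2436 and 96 to 314. The differences gave 13 to 156, 381 to 1179 and 59 to 127. E-m and m-l gave 32 to 138 and 51 to 225 after 2 g/l and 129 to 844 and 1 to 829 after 0.2 g/l, the difference in m-l 21 to 81, the courses 2849 to 3048 and 2399 to 3137, and list calls 167 to 182. Of 181 list calls 51 were lost in at least 1 such run.

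Of 1109 results for named genes, 1082 kept their call with centring and 27 lost it. With 1 spot per gene 46 lost it and 2 reversed, both early after 0.2 g/l: ARO1 (0.152) and SWI5 (0.15), whose spots disagree. Without single arrays 491 lost it in at least 1 run. The median correlation of the pulses at matched times was 0.306 (0.278 for genes with all values, 0.314 with quantile normalization). Signal over background is not analysed here, and the number of arrays limits the precision.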

Other observations

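The tests in this part of the signs at the end of both pulses were chosen only after the result was seen.

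The hexokinase gene HXK1, known to be repressed by glucose, first fell and then rose above its t=0 level after both pulses. After 2 g/l it was at -2.56 at 10 min and at 3.57 at 180 min, and after 0.2 g/l at -2.96 at 8 min, 3.16 at 45 min and 0.39 at 90 min. HXT5, for a transporter made in slow growth, was low in the middle window of both pulses (-1.44 ± 0.33 after 2 g/l and -1.38 ± 0.51 after 0.2 g/l, SD, n = 4 each). JEN1, for the lactate permease, was low early, at -1.69 ± 0.91 (SD, n = 4) and -1.86 ± 0.95 (SD, n = 5). The receptor gene STE2 and the protease gene BAR1 of the mating pathway were at 0.94 and 0.97 in the middle window after 2 g/l. FIG1, of the same list, was at -1.13 ± 0.25 (SD, n = 3) late after 0.2 g/l. On all arrays with a value STE2 was higher (mean 0.594) and FIG1 lower (mean -0.937), so their values are not particular to those windows.

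Early after the pulses 658 genes were higher in both and 426 lower in both. In the middle window these counts were 557 and 449, and in the late window 77 and 37. Whether the pulses share a t=0 sample is not known, and a shared one alone would give shared calls, so these counts were not tested. Across genes, the arrays of 0.2 g/l at 2, 4, 6, 8, 10 and 15 min were most like those of 2 g/l at 3, 7, 15, 15, 15 and 15 min (r = 0.52, 0.667, 0.733, 0.803, 0.759 and 0.68). Those at 20, 30, 45, 90, 120 and 150 min were most like 30, 120, 180, 180, 210 and 210 min (r = 0.654, 0.299, 0.227, 0.332, 0.66 and 0.613). Genes are not independent replicates, and these correlations were not tested.

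At the end of both pulses many genes had the same sign. Of 122 genes called in the final window of each pulse, 121 had the same sign and 1 the opposite, with 87 higher and 34 lower in both. Of the genes with at least 24 values, 213 had 1 sign on all arrays with a value, 104 higher and 109 lower. Among them were RNR1 (mean -2.00, SD 0.74), FIG1 (-0.94) and HHF1 (0.71), named after their values were seen. Members of the cytosolic ribosomal protein, glycolysis and iron lists were also among them, such as RPL31A (mean 1.03), TPI1 (0.61) and FIT2 (-2.19). The sign of these genes is therefore not particular to 1 window. A constant offset of the dyes or of the t=0 samples may contribute, since of 120 genes with both first values a share of 0.833 had the end sign on both first arrays. A lasting response that builds up was not decided either. The first values were 0.452 of the end values at the median (95% interval 0.391 to 0.544). The genes were chosen by their end values, which by itself lowers this ratio. The interval comes from resampling genes, which are not independent replicates. Without arrays with exchanged dyes or a t=0 sample against itself, an offset and a lasting response cannot be told apart.

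The agreement of spots given the same gene depended on where their identifiers lay. For 607 pairs whose identifiers lay within 180 of each other the median correlation over the arrays was 0.785, and for 509 pairs farther apart it was 0.187. The cause was not tested.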
